A study of Homo sapiens with 8 samples.

How the data were processed

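Total RNA of HepG2 and PLC5 cells, control or treated with 10 µM GSK343, was hybridized to 8 one-colour arrays, 2 in each of 4 groups. Amino-allyl antisense RNA was made by linear amplification and coupled to Cy5, per the labels' protocols. The deposited values were intensity values on a linear scale, 1 per probe and array, for 31741 probes. The scanner software, the background correction and any flags are not given in the sources used here. The deposited intensity values were whole numbers, some at or below 0, so a background had been subtracted, and their medians differed by more than 2 times between arrays, so no normalization between arrays was visible. Detection calls were not used here, so a probe is called dim here when its normalized intensity lies below 64, as a description only.

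The intensities were quantile normalized over the 8 arrays, floored at 1 and taken to log2. The share of probes at or below that floor before normalization was 6.99% and 0.706% in the HepG2 controls, 0.0063% and 0.904% in treated HepG2, 0% and 6.35% in the PLC5 controls and 1.27% and 0.0126% in treated PLC5. The median log2 fold change after normalization was -0.02 in HepG2 and -0.01 in PLC5. The design, the gene lists, the naming rule and the first set of alternatives were written before the data were examined. The design named no normalization for a linear table and listed quantile normalization as an alternative; it became the main setting once the values proved unnormalized, and the fit without normalization was added as an alternative.

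Probe symbols came from the platform annotation, which can be old. Of the probes, 24740 had 1 symbol, 977 several and 6024 none. Through the RefSeq gene table of assembly GRCh38.p14, 22722 symbols were current, 1948 were updated by a unique synonym and 70 matched nothing and were kept. A gene was represented by its 1-symbol probe with the highest mean over the 8 arrays, which gave 18336 genes, 5455 of them with further probes, and the text says where another probe of a named gene disagrees. Probes with several symbols were never named. Coordinates were not given in the sources used here.

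Group means were fitted in limma 3.58.1 (R 4.3.3) with lmFit on all 8 arrays, so that the 4 groups shared 1 estimate of the spread, and moderated with eBayes with a trend on intensity (4 residual and 4.75 prior degrees of freedom). The contrasts were treated minus control in HepG2 and in PLC5, the difference of these (PLC5 minus HepG2), and PLC5 minus HepG2 among the controls. P-values were two-sided and adjusted by Benjamini and Hochberg over all probes, with calls at an adjusted p under 0.05. The 48 gene lists were tested at gene level with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with lists of at least 5 measured genes. Camera with an estimated correlation was run beside it, and limma's fry, adjusted over the lists, was run for reference. Counts of list members are given over all probes and adjusted over the list alone. Overlap of calls between the lines was tested with Fisher's exact test. The lines share no control arrays, but they share the spread estimated for each probe.

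Genes were named by a rule: the 10 largest rises and 10 largest falls among called genes in each line with both treated arrays beyond both controls, the 5 largest on each side for the difference and for the controls, EZH2, EZH1, EED and SUZ12 everywhere, and up to 4 members with the largest change of each shifted list. Not every gene so chosen is printed. The same rule was applied to the brighter 50% of probes after the values were seen, and genes named outside the rule are marked as such.

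The fit was tested on 8 simulated arrays, made from the mean of each probe in each line and the spread estimated by the fit. Probes changed in treated HepG2 and genes of the simulated list all came from the brighter 50% of probes. Recovery of dim probes was therefore not tested. Of 50 changed probes of each size, 3 were called at a log2 change of 0.5, 29 at 1, 45 at 1.5 and 50 at 2, and 8 of 135 calls were unchanged probes. For PLC5 the simulated list was called and 0 of 48 unchanged lists were, and 0 of 49 unchanged lists were called in HepG2. Noise was drawn independently for each probe, so the simulation cannot show how often lists of genes that vary together are called wrongly. The median residual SD was 0.473 (log2) in the dimmest 10% of probes and 0.118 in the brightest 10%.

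The first alternatives were centring on the median, leaving out the dimmest 25% or 50% of probes, a pseudocount of 16, eBayes without trend or robust, a replicate block, fits on only the 4 arrays compared, log2 thresholds of 1, the median of all probes of a gene, an estimated inter-gene correlation and leaving out each array in turn, where the lone array of a group is assumed to vary like the others. Those added later were no normalization, quantile normalization within each line, a floor of 64, list tests with median centring, a crossed block and leaving out 33 probes that looked like missing spots. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.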

Results

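Gene expression was measured in 2 human liver cancer lines, HepG2 and PLC/PRF/5 (written PLC5 here), with and without 10 µM GSK343, a small-molecule inhibitor of the histone methyltransferase EZH2. EZH2 is the catalytic subunit of the Polycomb repressive complex PRC2, which silences developmental genes. RNA of each line was taken from control cells and from treated cells, with 2 one-colour arrays in each of the 4 groups and 8 arrays in all. The titles and the study's stated design give 16 h of exposure, while the treatment protocol of the same samples gives 6 h, so the time is taken as 16 h with that reservation. The stated question was which genes GSK343 regulates in these cells.

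Each array gave an intensity for 31741 probes, of which 24740 carried 1 gene symbol, and these stood for 18336 genes. The median deposited intensity was 239 and 226 in the HepG2 controls, 313 and 341 in treated HepG2, 495 and 415 in the PLC5 controls and 552 and 483 in treated PLC5. Before scaling, the median probe was therefore brighter after treatment by 0.49 (log2) in HepG2 and by 0.19 in PLC5, and all changes are given relative to that shift. Across probes, 2 arrays of a group correlated with r from 0.984 to 0.989, control and treated arrays of a line with r from 0.978 to 0.987, and arrays of different lines with r from 0.887 to 0.903. Errors are standard errors of the fit with 2 arrays per group, and the small number of arrays limits their precision. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values may measure technical spread alone. The labels also do not say whether control cells received the solvent, so its effect cannot be told apart from that of GSK343.

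In HepG2, GSK343 raised nearly the whole cholesterol synthesis pathway. MSMO1, a sterol methyl oxidase, rose by 1.61 ± 0.10 (log2, adjusted p = 0.000394), HMGCS1, which makes HMG-CoA, by 1.57 ± 0.11 and LSS, the lanosterol synthase, by 1.54 ± 0.15. Genes of the integrated stress response, which ATF4 and CHOP switch on when amino acids or protein folding fail, rose with them, among them the stress factor NUPR1 by 1.79 ± 0.12. Some immediate early genes, which follow growth factor signalling, went the other way, and EGR1 fell by 1.40 ± 0.12 (log2, adjusted p = 0.000718), although the call of their list was lost (adjusted p = 0.115 with an estimated correlation). No single gene of the PRC2 subunits, EZH2 included, passed the test.

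Of 20 measured cholesterol synthesis genes, 18 rose and 0 fell over all probes, and 19 rose and 0 fell adjusted over the list alone. Their median log2 fold change was 1.23 (camera adjusted p = 2.94e-22), and the call held with an estimated correlation (adjusted p = 0.0258). EBP, the sterol isomerase, rose by 1.57 ± 0.15. The second probe of MSMO1 gave 0.67 and that of LSS gave -0.12. Of 21 genes of fatty acid and triglyceride synthesis, 11 rose and 0 fell, and 13 rose and 1 fell adjusted over the list alone, with a median of 0.55 (adjusted p = 7.12e-10; adjusted p = 0.0487 with an estimated correlation). The largest of these rises were in ACSS2, the acetyl-CoA synthetase of the cytosol, with 2.25 ± 0.18, LPIN1, a phosphatidate phosphatase, with 1.80 ± 0.17, and the desaturase FADS2 with 1.57 ± 0.18. SCD, the stearoyl-CoA desaturase, rose 2.82-fold (standard error 0.10 in log2). Of 11 genes of SREBP regulation and lipoprotein uptake, 6 rose and 0 fell, and 6 rose and 1 fell adjusted over the list alone, with a median of 0.58 (adjusted p = 0.000561). That call was lost with an adjusted p = 0.115 with an estimated correlation. STARD4, a sterol carrier, rose by 1.63 ± 0.16 and TMEM97 by 0.84 ± 0.09.

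Of 33 genes of the integrated stress response, 17 rose and 2 fell in HepG2, and 19 rose and 2 fell adjusted over the list alone, with a median of 0.41 (adjusted p = 5.46e-08; adjusted p = 0.0487 with an estimated correlation). INHBE, an activin subunit made in liver, rose by 1.53 ± 0.17, the mitochondrial folate enzyme ALDH1L2 by 1.33 ± 0.18 and the lipoprotein receptor VLDLR by 1.33 ± 0.19. A second probe of ALDH1L2 gave 0.51 and was not called (adjusted p = 0.1). The members that fell, chosen for naming after their values were seen, were the amino acid carrier SLC38A2 (-0.39) and PPP1R15A (-0.82), which ends the response. Of 32 immediate early genes, 1 rose and 8 fell, and 1 rose and 11 fell adjusted over the list alone, with a median of -0.29 (adjusted p = 0.00212; adjusted p = 0.115 with an estimated correlation). DUSP5 and SPRY4, feedback inhibitors of MAP kinase signalling, gave -1.17 ± 0.12 and -0.98 ± 0.12, the call of SPRY4 being lost without normalization (adjusted p = 0.102). Of 31 proteasome genes, 0 rose and 4 fell, and 0 rose and 5 fell adjusted over the list alone, with a median of -0.23 (adjusted p = 0.00224; adjusted p = 0.115 with an estimated correlation). PSMC5 gave -0.55 ± 0.11 and PSMD2 -0.45 ± 0.10, and both lost their call without an array of HepG2, with adjusted p = 0.125 for PSMC5 without the first treated array and 0.139 for PSMD2 without the first control array. Of the 48 lists, 42 did not pass, with adjusted p from 0.0615 for ribosome biogenesis to 1.00.

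Among the single genes of HepG2 with the largest rise, MT1B, a metallothionein, rose by 3.97 ± 0.14 (adjusted p = 2.39e-05), from a normalized intensity of 135 to 2112. The cytokine gene IL17B rose by 2.60 ± 0.20 and the cytokine receptor gene IL21R by 2.84 ± 0.16. H1-5 and POLD3 ranked first by the fitted value, but their control arrays lay at the floor, so no fold is given. DYDC2, SH2B2 and CCDC18 rose from control levels below an intensity of 64, and so did CCDC91 and FAIM2, which lost their calls without the first treated HepG2 array (adjusted p = 0.128 and 0.155). Of the falls, KRT23, a keratin, fell by 1.95 ± 0.12 (adjusted p = 0.000394). Lower levels were also found for the calcium-binding protein gene S100A2 (-1.78 ± 0.15), the junction gene ESAM (-1.67 ± 0.18), FILIP1L (-1.66 ± 0.13) and the early response gene IER3 (-1.62 ± 0.15). The probes of PTPA and PPAT went from a level of 2873 and 1737 to the background (2.76 and 12.2). Of the 20 genes with the largest changes, 12 had a group below an intensity of 64. The calls of MACROD2-AS1 and RPL3 were lost without the second treated HepG2 array (adjusted p = 0.134 and 0.077), that of DRD3 with arrays centred on their median (0.307). Ranked again within the brighter 50% of probes, an addition made after the values were seen, the rises included ACSS2, the tubulin gene TUBB2B (2.14 ± 0.17), the organic anion carrier gene SLCO4C1 (2.07 ± 0.16) and ITIH1 (2.03 ± 0.15). The falls included GPRC5A (-1.58 ± 0.12) and the glucose carrier gene SLC2A3 (-1.58 ± 0.10).

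Of the genes of PRC2 subunits, limma called 0 of 12 in HepG2, also 0 adjusted over the list alone, while 1 was higher and 2 were lower at an unadjusted p under 0.05 (median -0.13, list adjusted p = 0.555). EZH2 gave -0.32 ± 0.11 (adjusted p = 0.117), EZH1 0.10 ± 0.16 (adjusted p = 0.736), EED 0.39 ± 0.15 (adjusted p = 0.139) and SUZ12 -0.13 ± 0.12 (adjusted p = 0.528). Genes reported as silenced by EZH2 had a median of 0.17 (list adjusted p = 0.528), with 5 of 28 higher and 2 lower, and 6 higher and 2 lower adjusted over the list alone. Developmental PRC2 targets had a median of 0.08 (list adjusted p = 0.853), with 3 of 100 higher and 2 lower, and 1 higher and 1 lower adjusted over the list alone. EZH2 and SUZ12 changed sign without normalization, so no direction is read for them. In limma's fry, which asks whether a list moved at all rather than more than other genes, 21 of 48 lists passed, the subunits (adjusted p = 0.0222) and the genes silenced by EZH2 (adjusted p = 0.00925) among them. The lists of markers of 4 other cell types were not shifted in HepG2 (adjusted p from 0.364 to 0.922).

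In all, limma called 2572 of 31741 probes in HepG2 (adjusted p under 0.05), 1540 higher and 1032 lower, and 981 and 633 genes at 1 probe per gene. With arrays centred on their median the split was 833 higher and 919 lower, and without normalization it was 5573 and 68. Without a trend in the variance model 1276 probes were called. The count fell to 1361 or 740 without the first or second HepG2 control array and to 523 or 580 without the first or second treated HepG2 array. Of 55 called values of the genes chosen by rule, 44 kept their call without each of the 8 arrays in turn.

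In PLC5, genes of the integrated stress response rose together, and the cholesterol pathway rose with them. TRIB3, a pseudokinase induced by ATF4, rose by 2.02 ± 0.14 (log2, adjusted p = 0.00063), and MSMO1 by 2.31 ± 0.10 (adjusted p = 6.2e-05). Genes of glycolysis and the hypoxia response rose as well, with ALDOC, an aldolase, higher by 2.03 ± 0.12 (adjusted p = 0.000515). Genes of DNA replication, mitosis and ribosome biogenesis shifted down as groups, mostly by amounts too small to pass the test gene by gene. HOXA3, HOXA4 and HOXA5, neighbours in a gene cluster that sets body axis identity in development, fell.

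Of 33 integrated stress response genes, 19 rose and 0 fell in PLC5, and 30 rose and 0 fell adjusted over the list alone, with a median log2 fold change of 0.89 (camera adjusted p = 1.45e-36; adjusted p = 0.00619 with an estimated correlation). INHBE rose by 1.77 ± 0.17, NUPR1 by 1.64 ± 0.12 and CHAC1, which degrades glutathione, by 1.59 ± 0.17, the last with adjusted p = 0.0625 without the first PLC5 control array. Of 20 cholesterol synthesis genes, 17 rose and 0 fell, and 18 rose and 0 fell adjusted over the list alone, with a median of 1.19 (adjusted p = 2.7e-32; adjusted p = 0.00636 with an estimated correlation). DHCR7, the last enzyme of the pathway, rose by 1.57 ± 0.11, and the isomerase IDI1 and HMGCS1 rose 2.84-fold and 2.83-fold (standard error 0.11 in log2 for both). Of 21 genes of fatty acid and triglyceride synthesis, 7 rose and 0 fell, and 12 rose and 0 fell adjusted over the list alone, with a median of 0.40 (adjusted p = 1.39e-10; adjusted p = 0.02 with an estimated correlation). ACSS2 rose by 1.97 ± 0.18, the elongase ELOVL6 by 1.35 ± 0.11 and SCD by 1.22 ± 0.10. Of 11 genes of SREBP regulation, 4 rose and 0 fell, and 7 rose and 1 fell adjusted over the list alone, with a median of 0.49 (adjusted p = 1.63e-05; adjusted p = 0.0394 with an estimated correlation). INSIG1, which holds SREBP in the endoplasmic reticulum, rose by 1.89 ± 0.20 in PLC5, and its HepG2 levels of 50.1 and 69.7 were near the background.

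Of 29 glycolysis and hypoxia genes, 8 rose and 0 fell in PLC5, and 17 rose and 0 fell adjusted over the list alone, with a median of 0.51 (adjusted p = 1.7e-13; adjusted p = 0.0116 with an estimated correlation). The kinase gene PFKFB4 rose by 1.73 ± 0.18 and the hypoxia marker NDRG1 by 1.35 ± 0.12. Of 43 autophagy genes, 5 rose and 0 fell, and 7 rose and 0 fell adjusted over the list alone, with a median of 0.20 (adjusted p = 1.32e-06; adjusted p = 0.021 with an estimated correlation). BNIP3L, a receptor for mitochondria, rose by 1.23 ± 0.14, with adjusted p = 0.0524 without the first treated PLC5 array, and TP53INP1 by 0.90 ± 0.10.

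Of 47 genes of DNA replication, 0 rose and 2 fell in PLC5, and 0 rose and 25 fell adjusted over the list alone, with a median of -0.35 (adjusted p = 3.47e-18; adjusted p = 0.00646 with an estimated correlation). The members that fell were the transcription factor gene E2F8 (-0.82 ± 0.13) and PCNA, the sliding clamp of DNA polymerase (-0.55 ± 0.10), the latter named after its values were seen. Of 46 mitosis genes, 0 rose and 1 fell, and 0 rose and 18 fell adjusted over the list alone, with a median of -0.33 (adjusted p = 4.37e-14; adjusted p = 0.0128 with an estimated correlation). That member was the proliferation marker MKI67 (-0.80 ± 0.13), and PLK1, a mitotic kinase, gave -0.68 ± 0.14 (adjusted p = 0.0787). The single calls of E2F8 and MKI67 were lost without an array, with adjusted p up to 0.137 without the second treated PLC5 array for E2F8 and 0.15 without the first for MKI67. Of 30 genes of ribosome biogenesis, limma called 0 over all probes, while 0 rose and 12 fell adjusted over the list alone and 15 were lower at an unadjusted p under 0.05, with a median of -0.33 (adjusted p = 2.4e-08; adjusted p = 0.02 with an estimated correlation). Of 26 DNA repair genes, limma called 0 over all probes, while 0 rose and 1 fell adjusted over the list alone and 11 were lower at an unadjusted p under 0.05, with a median of -0.27 (adjusted p = 2.98e-06; adjusted p = 0.0267 with an estimated correlation).

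A further 8 lists passed in PLC5 with the preset correlation and lost the call with an estimated one. Histone methyltransferases and demethylases (median -0.22, 0 of 24 called by limma, 0 higher and 1 lower adjusted over the list alone, 8 lower at an unadjusted p under 0.05) had adjusted p = 0.0623 with an estimated correlation. Immediate early genes (median 0.19, 2 of 32 higher, likewise 2 higher adjusted over the list alone) had adjusted p = 0.0751 with an estimated correlation. NF-kB and cytokine genes (median -0.20, 2 of 32 lower, 6 lower adjusted over the list alone) had adjusted p = 0.081 with an estimated correlation. The same adjusted p = 0.081 with an estimated correlation was found for p53 targets (median 0.09, 2 of 30 higher, 6 higher and 2 lower adjusted over the list alone). The proteasome (median -0.12, limma called 0 of 31, also 0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05) had it as well (adjusted p = 0.081 with an estimated correlation). Wnt targets (median -0.27, 0 of 20 called, 1 higher and 4 lower adjusted over the list alone, 1 higher and 6 lower at an unadjusted p under 0.05) had adjusted p = 0.12 with an estimated correlation. The BCL2 family (median 0.12, 2 of 18 higher, 5 higher and 2 lower adjusted over the list alone) had adjusted p = 0.134 with an estimated correlation. Endoplasmic reticulum chaperones (median 0.12, 2 of 24 higher, 4 higher adjusted over the list alone) had adjusted p = 0.219 with an estimated correlation. Of their members, the cell cycle inhibitor CDKN1A rose by 1.23 ± 0.12. The chaperone call was also lost with arrays centred on their median (adjusted p = 0.153) and without the first treated PLC5 array (0.156). The BCL2 call was lost with median centring (0.0607), with the dimmer 50% of probes left out (0.0647), and without the first PLC5 control array (0.0661) or the second treated one (0.112). The Wnt call was lost with the dimmer 50% left out (0.0676) and without that same treated array (0.0753). The remaining 30 lists did not pass, with adjusted p from 0.0619 for lysosomal genes to 0.991 for erythroid markers, and the lists of 4 other cell types had adjusted p from 0.382 to 0.991.

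Among single genes of PLC5 with the largest changes, ULBP1, a ligand of the NKG2D receptor of natural killer cells, rose by 1.96 ± 0.17 (adjusted p = 0.00133), although its other probe gave 0.57. LIPG, an endothelial lipase gene, rose by 1.92 ± 0.17 from a control level of 31.6, close to the background, and lost its call without normalization (adjusted p = 0.21). The probes of C2orf69, KIF15 and PTPA went from background in the controls (1.73, 4.44 and 12.6) to levels of 5905, 1560 and 2618. Of the falls, UBD, a ubiquitin-like modifier gene, fell by 1.43 ± 0.09 (adjusted p = 0.000562). HOXA5 fell by 1.35 ± 0.13 (adjusted p = 0.00176), HOXA4 by 1.29 ± 0.13 (adjusted p = 0.00217), and HOXA3 by 1.14 ± 0.11 (adjusted p = 0.00184). LRP12 (-1.22 ± 0.13) lost its call without normalization (adjusted p = 0.0542). A second probe gave -1.43 for HOXA5 and -0.39 for HOXA3. ADH1C, EDN1, KRTAP3-1, SLC12A5 and TIMP3 were called lower too, and each lost its call without several of the arrays, with adjusted p up to 0.192, 0.166, 0.144, 0.164 and 0.133. Those highest values came without the first PLC5 control array for ADH1C, KRTAP3-1 and SLC12A5 and without the first treated PLC5 array for EDN1 and TIMP3. Of these 20 genes, 6 had a group below an intensity of 64.

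Of the PRC2 subunits, limma called 0 of 12 in PLC5 too, with 0 higher and 2 lower adjusted over the list alone and likewise at an unadjusted p under 0.05 (median -0.04, list adjusted p = 0.277, fry adjusted p = 0.0267). EZH2 gave -0.53 ± 0.11 (adjusted p = 0.081), EZH1 -0.05 ± 0.16 (adjusted p = 0.923), EED -0.33 ± 0.15 (adjusted p = 0.353) and SUZ12 -0.02 ± 0.12 (adjusted p = 0.972). Genes reported as silenced by EZH2 had a median of 0.07 (list adjusted p = 0.413), with 1 of 28 higher and 1 lower, and 5 higher and 3 lower adjusted over the list alone (fry adjusted p = 0.0211, where 25 of 48 lists passed). Developmental PRC2 targets also had a median of 0.07 (list adjusted p = 0.395), with 0 of 100 higher and 1 lower, likewise 0 and 1 adjusted over the list alone.

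In PLC5, limma called 276 of 31741 probes, 208 higher and 68 lower, and 153 and 43 genes. With arrays centred on their median the split was 135 higher and 279 lower, and without normalization it was 128 and 11. Without a trend 78 probes were called, and with the dimmer 50% of probes left out 477. The count fell whichever array was left out: to 167 and 162 without a HepG2 control array, 130 and 136 without a treated HepG2 array, 117 and 158 without a PLC5 control array, and 118 and 125 without a treated PLC5 array (first and second array in each pair). Of 51 called values of the genes chosen by rule, 27 kept their call without each array in turn.

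**Figure D1:**
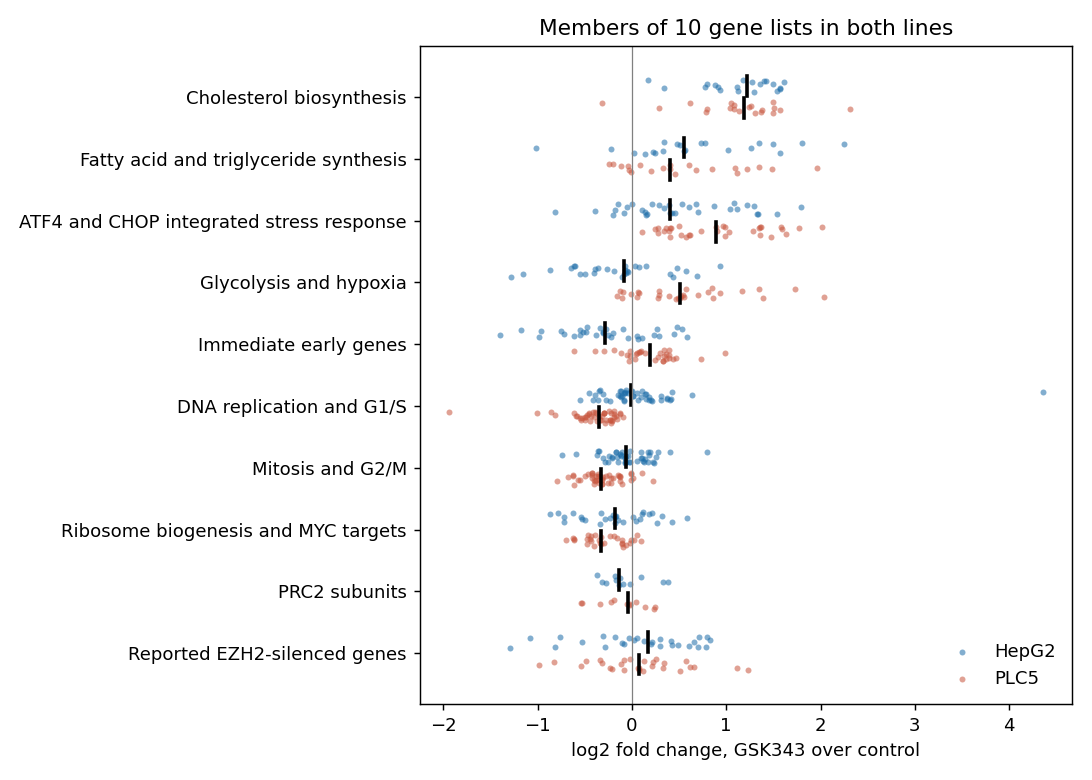
Log2 fold change (GSK343 over control, horizontal axis) of every measured member of 10 gene lists chosen for display after their values were seen, in HepG2 (blue) and PLC5 (red). Each point is 1 gene and each black bar the median of its list: the cholesterol medians are 1.23 and 1.19, while the glycolysis and hypoxia median is -0.09 in HepG2 and 0.51 in PLC5.

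The responses of both lines shared the sterol and stress genes. Among genes called higher, 79 were called in both lines, against 8.19 for independent lists (Fisher's exact test, two-sided p = 2.71e-59). ASNS, the asparagine synthetase, was one of them, with 1.11 in HepG2 and 1.36 in PLC5. Genes are not independent units and both lines share the spread of each probe, so the overlap p-values in both directions are descriptive. Among genes called lower, 5 were called in both lines, against 1.48 (Fisher's exact test, two-sided p = 0.0157), a number that fell to 1 without the first PLC5 control array, to 3 without either HepG2 control array and to 2 without any of the other 5 arrays. They were the endothelin gene EDN1, the matrix gene THBS1, the actin-binding gene TAGLN, UBD and KRTAP3-1. These names, and those of genes that moved in opposite directions, were chosen after their values were seen.

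The 84 genes that changed the same way were 42.9% of the 196 genes called in PLC5, and 6 genes were called in opposite directions, against 7.58 for independent lists. IGFBP1, a binding protein of insulin-like growth factors made by hepatocytes, fell by 0.51 in HepG2 and rose by 1.69 in PLC5. PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by 0.60 in HepG2 and rose by 0.86 in PLC5. GDF15, a stress cytokine, gave -0.55 and 0.94, FST, which binds activin, -0.45 and 0.68, HOXA3 0.55 and -1.14, and PTPA, as given above, switched between bright and background. With arrays centred on their median, 57 genes were higher and 50 lower in both lines. In the same order of arrays, the number that changed the same way was 54 and 49, 45 and 45, 43 and 53, and 45 and 54 when any 1 of them was left out. Across all 18336 genes the log2 fold changes of both lines correlated with r = 0.0957 and rho = 0.167, where genes are not independent replicates, and r was 0.00959 without the first treated PLC5 array and 0.151 without the second.

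With the preset correlation, all 6 lists that shifted in HepG2 also shifted in PLC5, 5 of them in the same direction, while the immediate early genes shifted down in HepG2 and up in PLC5. With an estimated correlation 3 of these 6 kept their call in HepG2, namely cholesterol synthesis, fatty acid synthesis and the integrated stress response, and these kept it in PLC5 too. The immediate early call was lost in both lines (adjusted p = 0.115 in HepG2 and 0.0751 in PLC5 with an estimated correlation), as was the proteasome call (0.115 and 0.081), and the SREBP call was lost in HepG2 (0.115). With the preset correlation, the other 12 lists passed in PLC5 alone by the threshold, which by itself does not show a difference between the lines.

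**Figure D2:**
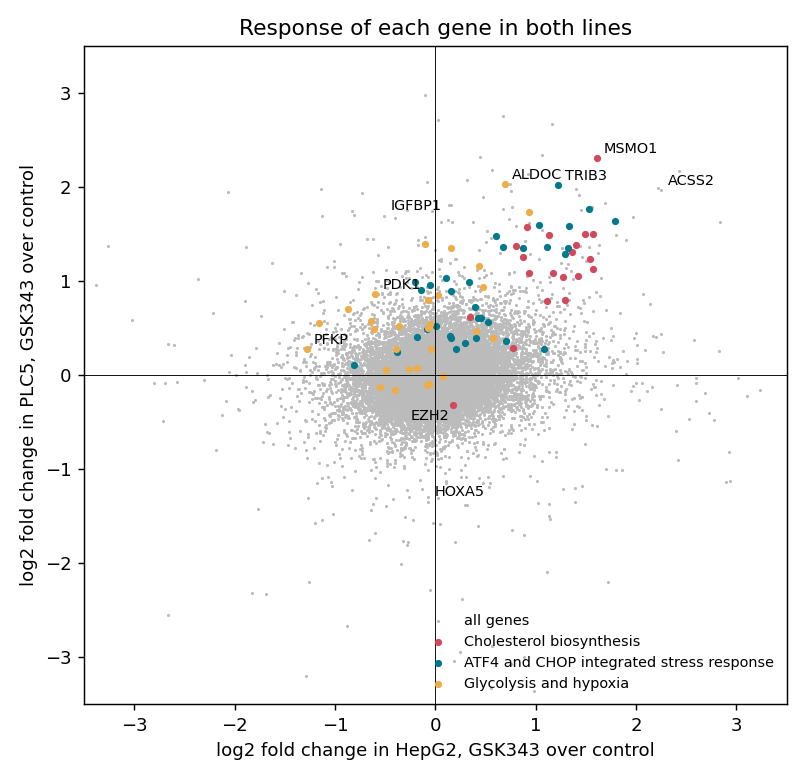
Log2 fold change of each gene in HepG2 (horizontal axis) and PLC5 (vertical axis), GSK343 over control, 1 point per gene, with 3 gene lists in colour and a few genes labelled, both chosen after the values were seen. The axes end at 3.5 on each side, which leaves out 34 of the 18336 genes, and the cholesterol and stress response genes lie mostly at the upper right.

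The difference between the responses was tested itself, as the change in PLC5 minus the change in HepG2. Glycolysis and hypoxia genes differed most as a group, and SLC2A3, a glucose carrier gene outside that list, fell in HepG2 and gave 0.23 ± 0.10 in PLC5, a difference of 1.81 ± 0.14 (adjusted p = 0.0028). Immediate early genes differed in the same sense, with EGR1 at 1.80 ± 0.16 (adjusted p = 0.00513). IGFBP1 had a difference of 2.21 ± 0.13 (adjusted p = 0.000398), with both treated arrays beyond both controls in each line. DNA replication genes went down in PLC5 relative to HepG2 as a group.

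Of 29 glycolysis and hypoxia genes, 6 had a positive and 0 a negative difference over all probes, and 18 and 0 adjusted over the list alone, with a median difference of 0.68 (camera adjusted p = 2.01e-13; adjusted p = 0.0403 with an estimated correlation). In HepG2 itself the list had a median of -0.09 and did not pass (adjusted p = 0.115), with 2 members higher and 7 lower, and 5 higher and 11 lower adjusted over the list alone. The glucose carrier gene SLC2A1 had a difference of 1.71 ± 0.22 (adjusted p = 0.0256), the carbonic anhydrase gene CA9 one of 1.57 ± 0.22 (adjusted p = 0.0317) and PFKP, a phosphofructokinase gene, one of 1.55 ± 0.21 (adjusted p = 0.0289). These 3 calls were lost without single arrays, with adjusted p up to 0.103 for SLC2A1 without the first treated HepG2 array and up to 0.127 for CA9 and 0.122 for PFKP without the first PLC5 control array. The calls of SLC2A1 and CA9 were also lost under 2 other scalings, with adjusted p up to 0.101 and 0.0742 without normalization. Of 32 immediate early genes, 4 had a positive and 0 a negative difference, and 13 and 2 adjusted over the list alone, with a median of 0.40 (adjusted p = 1.06e-06; adjusted p = 0.0432 with an estimated correlation). Of 33 stress response genes, 4 had a positive and 0 a negative difference, and 14 and 1 adjusted over the list alone, with a median of 0.33 (adjusted p = 2.09e-07; adjusted p = 0.0432 with an estimated correlation). Of 47 DNA replication genes, 0 had a positive and 1 a negative difference, and 0 and 11 adjusted over the list alone, with a median of -0.38 (adjusted p = 1.22e-08; adjusted p = 0.0403 with an estimated correlation). That 1 gene was POLD3, whose HepG2 controls lay at the floor. Of 46 mitosis genes, limma called 0, while 0 had a positive and 3 a negative difference adjusted over the list alone and 16 a negative one at an unadjusted p under 0.05, and the median was -0.32 (adjusted p = 1.06e-05; adjusted p = 0.0751 with an estimated correlation).

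Of 26 DNA repair genes, limma called 0, while 0 had a positive and 3 a negative difference adjusted over the list alone and 5 a negative one at an unadjusted p under 0.05, and the median was -0.22 (adjusted p = 0.0443; adjusted p = 0.289 with an estimated correlation). The DNA repair call was lost with quantile normalization within each line (adjusted p = 0.0563), with a floor of 64 (0.0932), and without each of 6 arrays. Those were the HepG2 control arrays (0.0904 and 0.121 in order), the treated HepG2 arrays (0.0576 and 0.0542), the first PLC5 control array (0.108) and the first treated PLC5 array (0.133). The other 42 lists did not pass, with adjusted p from 0.125 to 0.992. For genes silenced by EZH2 the difference had a median of -0.13, a mean of 0.01 and a camera direction of down (adjusted p = 0.879). For developmental PRC2 targets it had a median of -0.01, a mean of 0.05 and a direction of up (0.946). No direction is read from either.

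Within the brighter 50% of probes, the receptor kinase gene AXL had a difference of 1.99 ± 0.19 (adjusted p = 0.00664) and ITIH1 one of -2.30 ± 0.21 (adjusted p = 0.00494). DBP, a clock output gene, had one of -2.09 ± 0.21 (adjusted p = 0.00835), with 0.0626 without the first PLC5 control array, and its other probe gave -0.96 and was not called (adjusted p = 0.12). Differences for EZH2 (-0.21 ± 0.16, adjusted p = 0.522), EZH1 (-0.15 ± 0.23, adjusted p = 0.764), EED (-0.72 ± 0.21, adjusted p = 0.146) and SUZ12 (0.11 ± 0.17, adjusted p = 0.767) did not pass.

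In all, 221 probes differed, 104 with a positive and 117 with a negative difference, and without normalization the split was 22 and 288. The number was 19 without a trend, 93 with arrays centred on their median, 372 with robust eBayes and 455 with a floor of 64. The count fell to 124 and 81 without a HepG2 control array, 38 and 32 without a treated HepG2 array, 33 and 44 without a PLC5 control array, and 46 and 38 without a treated PLC5 array (first and second in each pair). Of 25 called values of the genes chosen by rule, 8 kept their call without each array in turn.

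**Figure D3:**
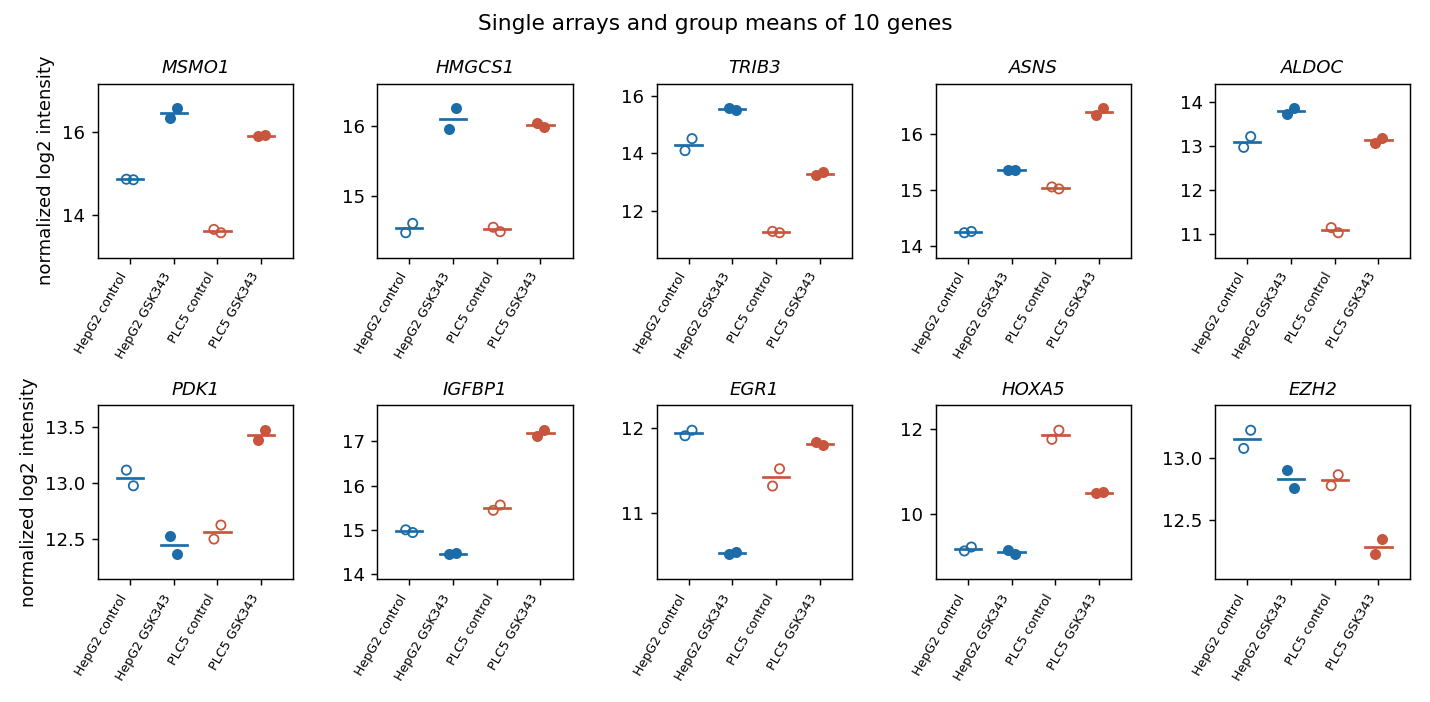
Normalized log2 intensity (vertical axis) of 10 genes chosen for display after their values were seen, in the 4 groups (horizontal axis). Each circle is 1 array, open for control and filled for GSK343, and each line is the mean of the 2 arrays of a group, with PDK1 and IGFBP1 lower in treated HepG2 and higher in treated PLC5.

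The control arrays of the lines differed far more than treated from control cells. PLC5 expressed VIM, the intermediate filament gene of mesenchymal cells, at a level of 114921 against 83.04 in HepG2 (difference 10.43 ± 0.28, log2), and LDHB, a lactate dehydrogenase gene, at 203336 against 53.6, near the background. HepG2 expressed AHSG, a secreted liver glycoprotein gene, at 71779 against 103 (-9.45 ± 0.11), and DLK1, a fetal liver gene, at 112382 against 174 (-9.34 ± 0.14). The cancer-testis antigen gene MAGEA4 was also higher in PLC5 (111003 against 71.4, close to the background, with 10.60 ± 0.19 at this probe and 8.38 at the other), and CRH and GJA1 were bright in PLC5 and at background in HepG2, so no fold is given for them. All of these had adjusted p under 0.05 and kept it without each array in turn.

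Genes of hepatocyte identity were lower in PLC5, with 25 of 33 called lower and 6 higher over all probes, the same counts adjusted over the list alone, and a median of -1.27 (adjusted p = 0.132 with an estimated correlation). Complement and coagulation genes had a median of -2.10, with 22 of 33 lower and 4 higher, and 23 lower and 4 higher adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). Wnt targets had a median of -2.14, with 16 of 20 lower and 1 higher, likewise adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). NF-kB and cytokine genes had a median of 1.02, with 18 of 32 higher and 5 lower, likewise adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). These lists and metallothioneins, p53 targets, bile acid genes and cholesterol genes (medians -3.29, -0.84, -0.87 and -0.56) and immediate early genes and TGF-beta targets (0.77 and 0.81) passed with the preset correlation, 10 lists in all. With an estimated correlation camera called 0 of the 48 lists, the last 6 with adjusted p = 0.172, 0.141, 0.172, 0.232, 0.141 and 0.172, while 18 had an unadjusted p under 0.05 with the preset correlation.

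Of PRC2, EED was higher in the PLC5 controls by 1.02 ± 0.15 (adjusted p = 0.00039, its other probe 0.68) and SUZ12 by 0.47 ± 0.12 (adjusted p = 0.00833). The latter had adjusted p = 0.147 when arrays were centred on their median and 0.0787 without the first HepG2 control array. EZH2 gave -0.33 ± 0.11 (adjusted p = 0.0356) and EZH1 -0.46 ± 0.16 (adjusted p = 0.0379), but both turned positive without normalization (0.55 each) and with quantile normalization within each line (0.35 and 0.33), so no direction is given for them. Without single arrays both calls were lost, with adjusted p up to 0.214 for EZH2 and 0.25 for EZH1 without the second HepG2 control array. Of the 10 genes with the largest differences, 6 had a group below an intensity of 64, and C2orf69, KIF15 and PPAT were bright in HepG2 and at background in the PLC5 controls.

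Between the controls, limma called 17555 probes, 8190 higher and 9365 lower in PLC5. Without normalization the split was 14186 and 1790, and with quantile normalization within each line it was 17256 and 2983.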

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

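The results here differ between the 2 lines by limma's test of the difference itself, PLC5 minus HepG2 in log2. Of the tests below, 2 on the glycolysis and hypoxia list were chosen before their results were seen. They are those on brightness-matched random lists and on further probes of the list genes. The others, that on pairs of probes of a gene included, were chosen after.

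By that test 221 probes differed. Among the genes of the naming rule, IGFBP1, bright in all groups, had a difference of 2.21. MT1B had one of -3.75, with PLC5 levels of 58.7 and 68.0 close to the level of 64 under which probes are called dim. For the others a group lay at or near the background, so that their fitted differences depend on the floor and on the background: PTPA 17.72, C2orf69 11.73, PPAT 8.91, KIF15 8.62, POLD3 -6.29, SLC12A5 -3.88, DYDC2 -3.65 and CCDC18 -3.13. Median differences of lists were 0.68 for glycolysis and hypoxia, 0.40 for immediate early genes, 0.33 for the integrated stress response, -0.38 for DNA replication, -0.32 for mitosis and -0.22 for DNA repair. The calls of mitosis and DNA repair were lost with an estimated correlation (adjusted p = 0.0751 and 0.289). The calls of PPAT, KIF15, POLD3, SLC12A5, DYDC2 and CCDC18 were lost without single arrays, with adjusted p up to 0.0764 for PPAT without the second treated HepG2 array and 0.145 for KIF15 without the second treated PLC5 array. For the other 4 the highest values came without the first PLC5 control array: 0.22 for POLD3, 0.163 for SLC12A5, 0.125 for DYDC2 and 0.136 for CCDC18.

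The first pattern is a set of probes at background (under 64) on both arrays of a pair and bright (over 1000) on the other arrays of the line, such as PTPA, PPAT, C2orf69 and KIF15. A loss shared by 1 control and 1 treated array alone cannot follow the treatment, yet 9 such cases were found in the 8 pairs of that kind, beside 6 in the 4 pairs of 1 group (a probe can count once in each line, as PTPA does), which argues against GSK343 switching genes on or off as the whole cause. The rate in those pairs over the rate in pairs of 1 group was 0.75 (1.13 and 1.5 cases per pair, exact Poisson p = 0.591). A further 11 probes were at background on 1 array and bright on the other 7, a stricter rule than that of the pairs. By the rule of the pairs, which asks only for the other arrays of the line, 33 probes were at background on 1 or 2 arrays. The cases above are among them. Spots lost independently on single arrays would coincide on 2 arrays far less often than they occur on 1. The counts therefore argue against independent loss of spots as the whole cause. PPAT was also at background in both PLC5 groups (2.52 and 8.52). A loss that arrays share for another reason was not tested. For any single gene, a response to GSK343 stays open.

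The second pattern is the larger number of calls in HepG2. Replicates did differ slightly less in HepG2 (median absolute deviation 0.262 and 0.255, against 0.284 and 0.275 in PLC5), but the fit gave both lines the same standard error for each probe and every treated over control ratio of single arrays spread more in HepG2 (lowest HepG2 over highest PLC5 value 1.12), so that cannot be the whole cause. Scaling cannot be the whole cause either, since HepG2 had at least 4.23 times as many calls under each other scaling tried (9.32 here). It did change the size of the excess, which reached 40.6 times without normalization. Across 2534 pairs of probes of a gene, both in the brighter 50% of probes, the covariance of their log2 fold changes was no larger in HepG2 (ratio 0.793, 95% interval 0.632 to 0.960) while the variance was (1.36, 1.08 to 1.68). The second probe had the same sign for 193 of 273 called genes in HepG2 and 35 of 35 in PLC5 (Fisher's exact test, p = 1.86e-05). Over all called genes with further probes, dim ones included, all of these had the same sign for 323 of 509 genes in HepG2 and 54 of 59 in PLC5. The called sets are not alike. At the same adjusted threshold 8.10% of probes were called in HepG2 and 0.870% in PLC5, so a call in PLC5 took a stronger change. The sign counts therefore cannot decide the question. By the covariance and the variance, part of the HepG2 calls may come from differences of single probes that both arrays of a group share. Transcript isoforms and the biology of the line stay open and were not tested.

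The third pattern is the different shift of glycolysis and hypoxia genes. The list call held under the other scalings, where the highest camera adjusted p of its difference was 5.77e-13. Median centring and no normalization differ by 1 constant per array, which moves the list and the other genes alike. Camera compares the list with the other genes, so such a constant can hardly change its result, and scaling is not excluded. The single calls of SLC2A1 and CA9 were lost without normalization (adjusted p = 0.101 and 0.0742). A movement of bright genes as a class was excluded, since the list median lay at percentile 100 of 10000 brightness-matched random lists (95% from -0.16 to 0.16). Differences of single probes cannot be told apart from a change of the genes, a verdict set after the values were seen. The further probes gave a median difference of 0.56, above the bound of 0.34 set beforehand against that explanation. The first probes of the same genes had a median difference of 0.30. However, only 4 further probes exist, their SD was 0.57 and 1 of them was not positive. A difference between the lines in biology stays open and was not tested.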

How the results depend on the processing

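No normalization, quantile normalization within each line, the floor of 64, list tests with median centring, the crossed block and the filter on missing spots were chosen only after the results were seen. For named genes, 2132 values kept direction and side of the threshold under an alternative other than leaving out an array, 207 lost their call, 57 gained one, 4 that were not called changed sign and 4 reversed; for shifted lists 251 were kept and 19 lost. Without 1 array, 1401 gene values were kept, 268 lost and 2 gained a call and 9 that were not called changed sign, and 230 list values were kept and 10 lost. The reversed values were the control differences of EZH2 and EZH1, which became 0.55 and 0.55 without normalization and 0.35 and 0.33 with quantile normalization within each line. For the controls that follows from the scaling, which sets the medians of the lines equal or not.

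With median centring 93 probes differed in response, 10 lists shifted in HepG2 and the correlation of the lines was 0.183, also its value without normalization, since both differ by 1 constant per array. Without normalization 5641 probes were called in HepG2 and 139 in PLC5, 10 lists shifted in HepG2 and 13 differed between the lines. With a floor of 64, 455 probes differed in response and r was 0.161, and without the missing-spot probes r was 0.169. With the dimmer 50% of probes left out, 477 probes were called in PLC5, 11219 of the fewer probes differed between controls and 128 genes changed the same way. Without a trend the counts were 1276 in HepG2, 78 in PLC5, 19 for the difference and 36 genes the same way, and with robust eBayes 372 probes differed in response. With a log2 threshold of 1 beside the adjusted p, 644, 110 and 8945 probes were called in HepG2, PLC5 and the controls and 36 genes the same way, and beside an unadjusted p 1118 in HepG2, 1189 for the difference, 9094 for the controls and 43 genes the same way. From only the 4 arrays compared, 114 probes were called in PLC5 and 48 genes the same way, with fewer degrees of freedom, and the difference could not be fitted. With an estimated inter-gene correlation 3 lists shifted in HepG2 and 10 in PLC5. The lists that lost their call in HepG2 had estimates below the preset 0.01. These were -0.0352 for SREBP regulation, -0.0131 for immediate early genes and -0.0136 for the proteasome. In PLC5, among the lists that lost their call, the chaperones had an estimate above the preset one (0.0832). The others had estimates from -0.0467 for Wnt targets to 0.00486 for NF-kB and cytokine genes. The values argue against a correlation larger than the preset one as the reason for those losses, the chaperones apart. Such a lost call therefore does not show that the genes of the list vary together. Apart from fewer arrays, fewer probes and stricter thresholds, the cause was not tested.

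With the replicate block 1574 probes were called in HepG2, 143 in PLC5 and 38 for the difference, and 54 genes changed the same way. With the block crossed in HepG2 2580 were called there. Over all probes, dim ones included, arrays of the same number did not deviate together (r from -0.114 to 0.00923). No pairing by number was therefore seen, which does not show that the arrays were not paired.

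Without 1 array, the counts ranged from 523 to 2262 in HepG2, 117 to 167 in PLC5, 32 to 124 for the difference, 14777 to 17268 for the controls and 43 to 54 for genes the same way, and r from 0.00959 to 0.151. Shifted lists ranged from 6 to 8 in HepG2, 16 to 22 in PLC5 and 5 to 7 for the difference. The lone array of a group was assumed to vary like the others. Weak signal limits the dim probes: 9 named values had both groups at the floor of 64 and no value there.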

Other observations

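The genes in this part were chosen after their values were seen, as was the test on HOX genes and that on brightness-matched genes, while the test on targets with low baseline was chosen before its result was seen.

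CYP1A1, the classic target of the aryl hydrocarbon receptor, rose in both lines, by 1.45 ± 0.13 (log2, adjusted p = 0.000894) in HepG2 and by 1.75 ± 0.13 (adjusted p = 0.000664) in PLC5. Other targets of that receptor were not called in either line: CYP1B1 gave -0.41 and 0.68, CYP1A2 0.03 and 0.15, AHRR -0.05 and -0.17 and TIPARP 0.22 and 0.72.

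Some genes of NKG2D receptor ligands, for which no list was tested, were called. ULBP1 rose by 0.76 ± 0.17 in HepG2, from a level near the background, and by 1.96 ± 0.17 in PLC5, MICB rose by 0.53 ± 0.11 and 0.69 ± 0.11, and MICA rose by 0.82 ± 0.12 in HepG2 and gave 0.48 ± 0.12 (adjusted p = 0.113) in PLC5. ULBP2, ULBP3, RAET1E, RAET1G and RAET1L were not called in either line.

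MT1B rose in HepG2 by 3.97 ± 0.14, while MT1E gave -0.18, MT1X -0.00, MT2A 0.20 and MT1A 0.06 there and were not called. Of the 7 genes of the metal response list, MTF1, the factor that switches metallothioneins on, was the other one called higher in HepG2 (0.84 ± 0.15, adjusted p = 0.0161).

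HOXA3, HOXA4 and HOXA5 fell in PLC5, and their differences between the lines passed (-1.69 ± 0.15, -1.21 ± 0.18 and -1.27 ± 0.18, adjusted p = 0.00494, 0.0336 and 0.0311). Among HOX genes, 3 of 10 HOXA genes and 0 of 28 others were called lower in PLC5 (Fisher's exact test, two-sided p = 0.0142). That test counts the same 3 genes that prompted it, so it restates the observation and does not show whether the fall is confined to this cluster.

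PRC2 target lists did not shift, and a rise only of targets with a low baseline was tested. In HepG2 the 63 dimmer targets had a median of 0.21 and the 63 brighter ones -0.05, a gap of 0.27, above the bound of 0.2 set beforehand, and in PLC5 the gap was 0.08. Other genes matched in brightness had a gap of 0.10 in HepG2, with 95% of 2000 draws from -0.09 to 0.28. A rise of dim targets cannot be told apart from dim genes rising whether or not they are targets, because the gap of the targets lies within the range of the matched genes.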
